A study of Homo sapiens with 9 samples.

How the data were processed

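Poly(A) RNA of 9 libraries from K562 cells was measured in 3 groups of 3: control (DMSO), DFMO at 1 mM and sardomozide at 5 uM, each for 72 h. Groups and replicate numbers were taken from the labels, which name each library once. The general treatment text in the labels names sardomozide and DMSO for 72 h. The dose of DFMO, its time and its DMSO control come from the design text of the series alone, and the solvent of DFMO is not given in the sources used here. Per the labels' protocols, RNA was selected for poly(A) tails and read as pairs of 150 bases. The submitters' processing notes name STAR 2.7.1a, DESeq2 and the build hg38 (GRCh38), without the role or order of each. The tool that counted reads, its strand setting, the annotation release and any filter are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be assigned with certainty.

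The authors deposited 2 tables, one per drug against control, of 62757 genes each. Per the file headers and the values, each holds raw counts per gene and library as whole numbers. Beside them stand the authors' normalized signal values, which are the counts divided by 1 size factor per library set within that table. The authors' deposited log2 fold changes are shrunken toward 0 for genes with few counts, and their p-value and adjusted p columns are those of DESeq2. Raw counts of the 3 control libraries were the same in both tables (0 values differed), so all 9 libraries could be fitted together from the counts. The normalized signal was used to recover the authors' size factors within each table and was never compared between tables. Another 12 columns of values per library were not used. No line failed to name a gene. Gene symbols were matched to 62130 identifiers exactly and to 509 without the version number, and 118 stayed unnamed. Gene types and coordinates come from GENCODE 29 on GRCh38.

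Total counts per library were 27501744, 26620996 and 26553339 (control), 34651963, 22157443 and 19954117 (DFMO) and 26713000, 29518069 and 28067317 (sardomozide). No count in any library was found for 28762 of the genes given. Counts of replicates differed by more than sampling noise, with chi-square per degree of freedom of 1.58 to 4.86 over genes with 20 or more counts in a pair, so no library was counted as a copy of another. Depth limits genes near the floor, and intervals from counts would cover counting error alone.

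Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr over the 3 groups (minimum count 10, minimum total 15), which left 16947. Libraries were scaled by TMM, with factors of 1.0438 to 1.0528 for control, 0.9132 to 0.9202 for DFMO and 1.0224 to 1.0533 for sardomozide, and CPM values printed are TMM-scaled. A robust quasi-likelihood model with a term for group gave 3 two-sided contrasts, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 change is its size divided by the square root of the F statistic. Before the data were examined, 32 gene lists were written from textbook knowledge, with 1102 members in all, some in more than 1 list. Lists were tested with camera on log2 CPM with a preset correlation of 0.01 and adjustment over the 32 lists. With the correlation estimated for each list, the histone list alone kept its call, under sardomozide against control and against DFMO. The rotation test fry was run as well, which asks whether the genes of a list move on balance one way and does not compare them with other genes.

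The genes to be named were also fixed before the data were examined. They are the 10 largest rises and 10 largest falls for each drug (5 each for the direct comparison) among protein-coding genes past the threshold whose libraries did not overlap and whose mean CPM was at least 5, all polyamine and iron genes, up to 4 members of each list past its threshold with the smallest p-values, and a fixed set with TFRC, FTH1, FTL, SLC7A11, GPX4, ACSL4, CHAC1, HMOX1, MYC, ODC1, AMD1, SAT1, SRM, SMS, OAZ1 and AZIN1. Genes with nearly identical copies, such as globins, histones, ribosomal protein genes with pseudogenes and HSPA1A with HSPA1B, have uncertain counts where reads were shared. Some genes that the rule allows are not reported here.

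The pipeline was tested on simulated counts with 50 genes changed at each fold. Changes of 2-fold were recovered in 100% of cases for DFMO, 98% for sardomozide and 96% for the direct comparison, and changes of 1.25-fold in 70%, 60% and 66%. False calls were made for 11 of 16494, 13 of 16502 and 17 of 16508 genes. A raised list was called in each simulated comparison and 0 of 31 other lists were. Simulated genes were drawn independently of each other, so this does not show how often camera makes false calls for lists whose genes move together.

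Alternatives fixed beforehand were RLE size factors, no filter, a strict filter (5 CPM in at least 3 libraries), DESeq2 1.42.0, the 6 libraries of a comparison alone, the replicate number as a block, a test against a fold of 1.5, and each library left out in turn. After the data were seen, the median of each list past the threshold was set beside that of 10 protein-coding genes per member matched on expression, or on transcript length and expression, with 95% intervals from 2000 bootstrap draws. Correlations between the drugs were set beside 100 simulated sets without any effect. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.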

Results

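RNA with poly(A) tails was sequenced from K562 cells, a human chronic myelogenous leukemia line that can express erythroid genes. The cells had been exposed for 72 h to DMSO as the control, to 1 mM DFMO or to 5 uM sardomozide. DFMO (difluoromethylornithine) irreversibly inhibits ornithine decarboxylase, the enzyme that makes putrescine. Sardomozide inhibits S-adenosylmethionine decarboxylase, which supplies the aminopropyl groups of spermidine and spermine. The title of the series ties these drugs to polyamines, labile iron and ferroptosis, a form of cell death driven by iron and lipid peroxidation. Each of the 3 groups had 3 libraries. Total counts were 26553339 to 27501744 in the control libraries, 19954117 to 34651963 in the DFMO libraries and 26713000 to 29518069 in the sardomozide libraries. No source used here says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Levels below are CPM, counts scaled to a common library total, as mean ± SD over the 3 libraries of a group. Changes are log2 values ± SE from edgeR's quasi-likelihood test, with p-values adjusted over 16947 tested genes.

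Replicates lay close together. Pearson correlations of log2 CPM between libraries of a group were 0.9975 to 0.9984 across genes, which are not independent replicates. On the 1000 most variable genes, the first principal component held 66.6% of the variance and set the sardomozide libraries (44.1 to 45.0) apart from DFMO (-14.8 to -14.0) and control (-30.6 to -29.9). The next component held 26.5% and set DFMO apart, at 25.7 to 28.1. Transcripts coded in mitochondrial DNA took 5.77 ± 0.11% of control counts, 5.39 ± 0.34% under DFMO and 3.30 ± 0.04% under sardomozide. Cytosolic ribosomal protein transcripts took 7.03 ± 0.14%, 8.12 ± 0.12% and 5.62 ± 0.13% of counts in the same order.

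The comparison of DFMO with control asked which transcripts change when ornithine decarboxylase is inhibited. AMD1, which encodes the target of sardomozide, rose 7.40-fold under DFMO, from 98.3 ± 3.46 to 728 ± 26.2 CPM (log2 change 2.89 ± 0.04, adjusted p = 1.065e-40). ODC1, which encodes the target of DFMO itself, rose 1.92-fold, from 455 ± 7.31 to 873 ± 18.5 CPM. SAT1, whose enzyme acetylates spermidine and spermine for export or breakdown, was 8.27-fold lower, falling from 67.1 ± 5.72 to 8.11 ± 0.08 CPM (log2 change -3.05 ± 0.07, adjusted p = 1.322e-32). TFRC, the receptor that takes up transferrin-bound iron, rose 2.64-fold from 380 ± 2.83 to 1003 ± 27.7 CPM. Most listed chaperone and ribosome biogenesis genes rose, while most targets of the stress factor ATF4 and most erythroid genes fell, by the counts and tests given below.

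Polyamine genes moved in both directions under DFMO. OAZ1 and OAZ2 encode antizymes, which bind ornithine decarboxylase and send it to the proteasome, and they changed by -1.23 ± 0.03 and -1.59 ± 0.06 on the log2 scale. AZIN1, which sequesters antizyme, rose by 1.21 ± 0.04. Spermidine synthase (SRM) rose by 1.03 ± 0.03 and spermine synthase (SMS) by 0.29 ± 0.04. The spermine oxidase gene SMOX changed by -0.86 ± 0.08, and ARG2, an arginase that yields ornithine, by -1.83 ± 0.08. EIF5A, the protein that carries the spermidine-derived residue hypusine, rose by 0.84 ± 0.03, and the hypusine enzymes DHPS and DOHH each rose by 0.75. ATP13A3, a polyamine transporter gene, rose by 0.49 ± 0.04. Of the 23 tested members of the polyamine metabolism list, 10 rose, 9 fell and 4 did not pass the threshold. The list as a whole did not stand out by camera (adjusted p = 0.724), with a median of 0.08, a mean of -0.11 and a test that pointed up. AMD1 lies on chromosome 6 from 110874770 to 110895713 (ENSG00000123505.19), ODC1 on chromosome 2 from 10439968 to 10448504 (ENSG00000115758.14), SAT1 on chromosome X from 23783173 to 23786226 (ENSG00000130066.17) and OAZ1 on chromosome 19 from 2269509 to 2273490 (ENSG00000104904.12), all in GRCh38 and annotated as protein-coding.

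**Figure D1:**
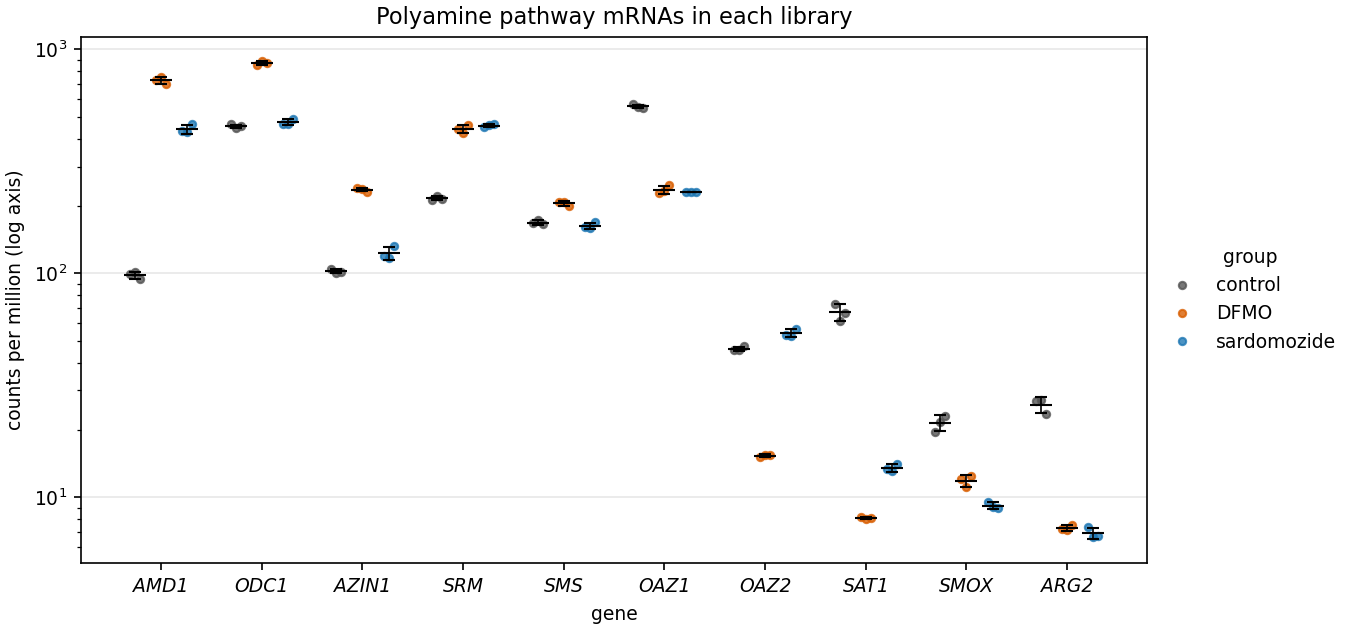
CPM of polyamine genes, on a log axis, in each of the 9 libraries (points), with the mean and SD of the CPM of each group of 3. AMD1 lies at 98.3 CPM in control, 728 in DFMO and 442 in sardomozide, and SAT1 at 67.1, 8.11 and 13.5 CPM.

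Iron genes moved in both directions under DFMO. Beside TFRC, a rise was seen for the ferrireductase gene STEAP3 (0.67 ± 0.05) and the heme exporter gene FLVCR1 (0.59 ± 0.05). Falls included the divalent metal transporter SLC11A2 (-0.98 ± 0.04), the second transferrin receptor TFR2 (-0.84 ± 0.04), the mitochondrial iron importer SLC25A37 (-0.78 ± 0.04) and ferroportin, SLC40A1 (-0.36 ± 0.05). The ferritin heavy chain gene FTH1 had a change of -0.04 ± 0.03 (adjusted p = 0.252), and passed the threshold with the strict filter (-0.10, adjusted p = 0.0016746). The light chain gene FTL rose by 0.11 ± 0.03 (adjusted p = 0.00259), a call that the strict filter ended (adjusted p = 0.112). Over all settings but the test against a fold of 1.5, no other call of these ferritin genes changed. In the list of iron uptake, storage and export, 10 of 27 tested members rose, 9 fell and 8 did not pass (11 and 9 adjusted over the list alone, camera adjusted p = 0.847). HMOX1, a heme-degrading enzyme often used as a marker of oxidative stress, had 0 reads in the control and DFMO groups and 3 in the sardomozide group, below the filter. TFRC lies on chromosome 3 from 196027183 to 196082189 (ENSG00000072274.14).

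Beside TFRC and SAT1, the ferroptosis genes fixed for naming changed by less than 2-fold under DFMO. GPX4, which reduces phospholipid hydroperoxides, rose 1.17-fold from 236 ± 4.70 to 275 ± 3.60 CPM (adjusted p = 1.413e-07). SLC7A11, the cystine importer, fell to 72.8 ± 0.58 from 109 ± 3.56 CPM (log2 change -0.58, adjusted p = 1.388e-16). CHAC1, which degrades glutathione, was 1.91-fold lower (log2 change -0.93 ± 0.05). ACSL4, which activates polyunsaturated fatty acids for phospholipids, had a change of -0.04 ± 0.05 (adjusted p = 0.495). Of 34 ferroptosis suppressors, 18 rose, 8 fell and 8 did not pass (median 0.10, camera adjusted p = 0.106, and 0.02476 with no low-count filter). Of 25 promoters, 9 rose, 6 fell and 10 did not pass (adjusted p = 0.856), with a median of 0.02, a mean of -0.12 and a test that pointed up. Among 31 NRF2 targets, 14 rose and 14 fell (adjusted p = 0.903), with a median of 0.02, a mean of -0.05 and a test that pointed up.

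Genes of ribosome production, respiration and protein folding rose under DFMO. All 44 tested members of the MYC and ribosome biogenesis list rose, among them UTP20 (1.84 ± 0.04), RRP9 (1.66 ± 0.05) and NOP56 (1.10 ± 0.03), which process ribosomal RNA. The list median was 0.79 (camera adjusted p = 3.934e-17), with adjusted p = 0.1425 with an estimated correlation. MYC rose by 0.40 ± 0.03. All 76 cytosolic ribosomal protein genes rose, with a median of 0.42 (adjusted p = 2.119e-16), and adjusted p = 0.379 with an estimated correlation. Protein-coding genes matched to them on expression had a median of 0.31, and those matched on length and expression 0.41, a comparison added, like all those with matched genes below, after the data were seen. RPS26 rose by 1.36 ± 0.04 and RPS15 by 0.83 ± 0.03. Of 76 nuclear genes of the respiratory chain, 69 rose, none fell and 7 did not pass (70 rose adjusted over the list alone). Their median was 0.49 (adjusted p = 3.987e-14), with adjusted p = 0.2749 with an estimated correlation, beside 0.24 in genes matched on length and expression. NDUFB2 and NDUFS5, both of complex I, rose by 1.13 ± 0.04 and 1.08 ± 0.04. In the heat shock list, 22 of 24 genes rose and none fell (median 0.90, adjusted p = 1.893e-10), with adjusted p = 0.2749 with an estimated correlation. HSPA8, the constitutive HSP70 chaperone, rose 6.85-fold from 350 ± 4.82 to 2395 ± 42.7 CPM, and HSPH1 rose 3.11-fold. HSPA1A and HSPA1B rose 4.54-fold and 4.04-fold, values that are uncertain because these copies are nearly identical and can share reads.

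Cell cycle, sterol and iron-sulfur genes rose by smaller amounts. In the S phase list 29 of 43 genes rose, 4 fell and 10 did not pass (30 and 4 adjusted over the list alone, median 0.31, camera adjusted p = 6.241e-05), with adjusted p = 0.4667 with an estimated correlation. The replication genes MCM4 (0.94 ± 0.03) and UHRF1 (1.03 ± 0.04) were among them. In the G2 and M phase list 34 of 54 genes rose, 10 fell and 10 did not pass (median 0.19, adjusted p = 0.00703), with adjusted p = 0.4667 with an estimated correlation and 0.0593 with the strict filter. Genes matched on expression had a median of 0.195, and the median of the differences between members and their matched genes was -0.006 (95% interval -0.104 to 0.112). Genes of iron-sulfur cluster assembly rose in 19 of 28 cases and fell in 5 (20 and 5 adjusted over the list alone, median 0.32, adjusted p = 0.00863), with adjusted p = 0.379 with an estimated correlation and 0.06134 with the strict filter. Less genes matched on length and expression, their median was 0.128 (-0.137 to 0.388). CISD1, an outer mitochondrial membrane iron-sulfur protein, rose by 1.19 ± 0.05, and the cysteine desulfurase NFS1 by 0.70 ± 0.05. Of 25 cholesterol genes 15 rose and 6 fell (median 0.29, adjusted p = 0.025), with adjusted p = 0.3966 with an estimated correlation and 0.126 with the strict filter. Less genes matched on expression it was 0.144 (-0.049 to 0.362).

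Targets of ATF4, the transcription factor of the integrated stress response, fell under DFMO in 34 of 41 cases, with 6 rises and 1 gene not past the threshold. Their median was -0.59 (camera adjusted p = 1.146e-07), with adjusted p = 0.2749 with an estimated correlation. DDIT4, an inhibitor of mTORC1, was 2.49-fold lower, falling from 1342 ± 14.8 to 538 ± 22.5 CPM. The mitochondrial folate enzyme ALDH1L2 and the gluconeogenic enzyme PCK2 were 2.95-fold and 2.53-fold lower. In the globin and erythroid list 27 of 40 genes fell, 4 rose and 9 did not pass (27 and 6 adjusted over the list alone, median -0.58, adjusted p = 6.241e-05), with adjusted p = 0.165 with an estimated correlation. The erythropoietin receptor EPOR changed by -1.81 ± 0.07. Heme biosynthesis genes fell in 13 of 19 cases and rose in 3 (median -0.30, adjusted p = 0.0134), with adjusted p = 0.2749 with an estimated correlation. FECH, an enzyme of that pathway, changed by -0.67 ± 0.04. Of 27 replication-dependent histone genes 19 fell and 2 rose (median -0.65, adjusted p = 0.00199), with adjusted p = 0.1425 with an estimated correlation. H1-2 changed by -0.98 ± 0.03. These mRNAs lack poly(A) tails, so their counts also depend on how the RNA was selected.

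CDK inhibitors and p53 targets fell under DFMO in 15 of 24 cases and rose in 5 (median -0.31, camera adjusted p = 0.04), with adjusted p = 0.2749 with an estimated correlation. That call ended without control replicate 2 (adjusted p = 0.05449) and without DFMO replicate 1 (0.05453), within a range of 0.02526 to 0.05453 over the other settings of this test. The p53-induced gene TP53INP1 changed by -2.31 ± 0.10 and the cyclin-dependent kinase inhibitor CDKN1C by -1.43 ± 0.06, while the nuclease gene AEN rose by 1.20 ± 0.04. Interferon-stimulated genes fell in 14 of 19 cases and rose in 3 (median -0.78, adjusted p = 0.04), with adjusted p = 0.2749 with an estimated correlation. The strict filter ended this call (adjusted p = 0.608), as did a fit of the 6 libraries alone (0.0555). Less genes matched on expression, the interferon list median was -0.431 (-0.614 to -0.184). STAT2 changed by -0.54 ± 0.04, while BST2 rose by 0.56 ± 0.04.

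By the naming rule, the genes with the largest rises under DFMO included, after AMD1 and HSPA8, the sialic acid receptor SIGLEC6 (5.06-fold), the RNA polymerase I subunit POLR1G (4.12-fold), PHLDA2 (3.80-fold), the cytokine signalling inhibitor SOCS1 (3.75-fold), VASN (3.71-fold) and the neurofilament gene NEFH (3.66-fold). The largest fall was in SCN4A, a muscle sodium channel gene on chromosome 17 from 63938554 to 63972918 (ENSG00000007314.12), at 0.90 ± 0.40 against 13.5 ± 0.58 CPM, 14.4-fold lower. PRSS8, TUFT1, RIMS3, MYO1F and TLCD2 were 8.14-fold to 9.23-fold lower, and the receptor kinase ERBB3 and the transcription factor NFATC4 were 7.53-fold and 7.17-fold lower. Over all genes, 11450 of 16947 passed the threshold, 5614 up and 5836 down. In 11005 of those that passed, the DFMO libraries lay wholly on one side of the controls. Chance gives 10% for 3 against 3 among genes not chosen by p-value, a rate that does not apply to genes already past the threshold. Changes of at least 2-fold were fewer, with 597 rises and 1809 falls. In the authors' deposited table, an adjusted p under 0.05 was given for 10096 genes, 5146 up and 4950 down, and 9866 of these were among the calls made here with the same direction. Against a fold of 1.5, the count of calls was 3182. Adjusted over the list alone, the lists named for DFMO gave the same counts as over all genes, apart from those stated.

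The comparison of sardomozide with control asked the same of S-adenosylmethionine decarboxylase. CHAC1, a target of the integrated stress response, was 72.2-fold lower, at 0.78 ± 0.17 against 56.3 ± 2.81 CPM (log2 change -6.17 ± 0.10, adjusted p = 5.304e-39). PHGDH, which starts serine synthesis, was 37.6-fold lower, at 10.2 ± 0.54 against 386 ± 5.21 CPM. ALAS2, which starts heme synthesis in red cell precursors, rose 12.8-fold from 15.1 ± 1.58 to 194 CPM (SD 6) (log2 change 3.68 ± 0.05, adjusted p = 6.097e-41), and embryonic zeta globin, HBZ, rose 10.6-fold from 29.4 ± 1.70 to 311 ± 14.6 CPM. The histone transcript H1-2 was 9.32-fold lower.

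In the polyamine pathway AMD1 rose 4.49-fold under sardomozide, to 442 ± 20.1 CPM (log2 change 2.17 ± 0.04, adjusted p = 2.777e-37). SAT1 was 4.96-fold lower (-2.31 ± 0.06), and the antizyme gene OAZ1 was 2.41-fold lower (-1.27 ± 0.03). SRM rose by 1.08 ± 0.03 and AZIN1 by 0.27 ± 0.04, and OAZ2 rose by 0.23 ± 0.05. ODC1 stood at 474 ± 15.5 CPM, a change of 0.06 ± 0.03 that did not pass the threshold (adjusted p = 0.1045). It passed under 5 of the alternative settings, among them without sardomozide replicate 2 (0.08, adjusted p = 0.048499), with adjusted p-values of 0.0106 upward across the settings tried. SMS had a change of -0.05 ± 0.04 (adjusted p = 0.222), which passed with the strict filter (-0.12, adjusted p = 0.0012787). SLC7A1, an importer of arginine and ornithine, was 4.12-fold lower, and ARG2 and SMOX changed by -1.91 ± 0.08 and -1.23 ± 0.08. DOHH and EIF5A rose by 0.91 ± 0.05 and 0.35 ± 0.03. Of 23 list members 9 rose, 10 fell and 4 did not pass (median -0.05, camera adjusted p = 0.708).

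Iron genes also moved in both directions under sardomozide. FTH1 rose 1.45-fold from 947 ± 31.8 to 1373 ± 23.0 CPM (adjusted p = 1.017e-18), FTL 1.26-fold, and NCOA4, which delivers ferritin to the lysosome, 1.64-fold. TFRC rose 1.48-fold to 563 ± 9.67 CPM (log2 change 0.57 ± 0.03, adjusted p = 1.825e-19). Ferroportin, SLC40A1, was 2.28-fold lower and the ferroxidase HEPH 1.75-fold lower. SLC39A14, which imports iron not bound to transferrin, changed by -0.61 ± 0.04, TFR2 by -0.48 ± 0.04 and SLC11A2 by -0.33 ± 0.04. ACO1, the cytosolic aconitase that can bind iron-responsive elements, rose by 0.46 ± 0.04. Of the 27 tested iron genes 14 rose, 11 fell and 2 did not pass (14 and 12 adjusted over the list alone, camera adjusted p = 0.761).

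Among ferroptosis genes, SLC7A11 was 7.10-fold lower under sardomozide, at 15.3 ± 0.43 CPM (log2 change -2.83 ± 0.05, adjusted p = 4.105e-38). It lies on chromosome 4 from 138164097 to 138242349 (ENSG00000151012.13). ACSL4 was 1.57-fold lower (-0.65 ± 0.05) and GPX4 rose 1.10-fold to 260 ± 1.16 CPM (adjusted p = 0.000182). Of the suppressors 14 rose, 19 fell and 1 did not pass (median -0.22, camera adjusted p = 0.392), and of the promoters 11 rose, 12 fell and 2 did not pass (adjusted p = 0.761). NRF2 targets rose in 10 and fell in 14 of 31 cases (adjusted p = 0.526).

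**Figure D2:**
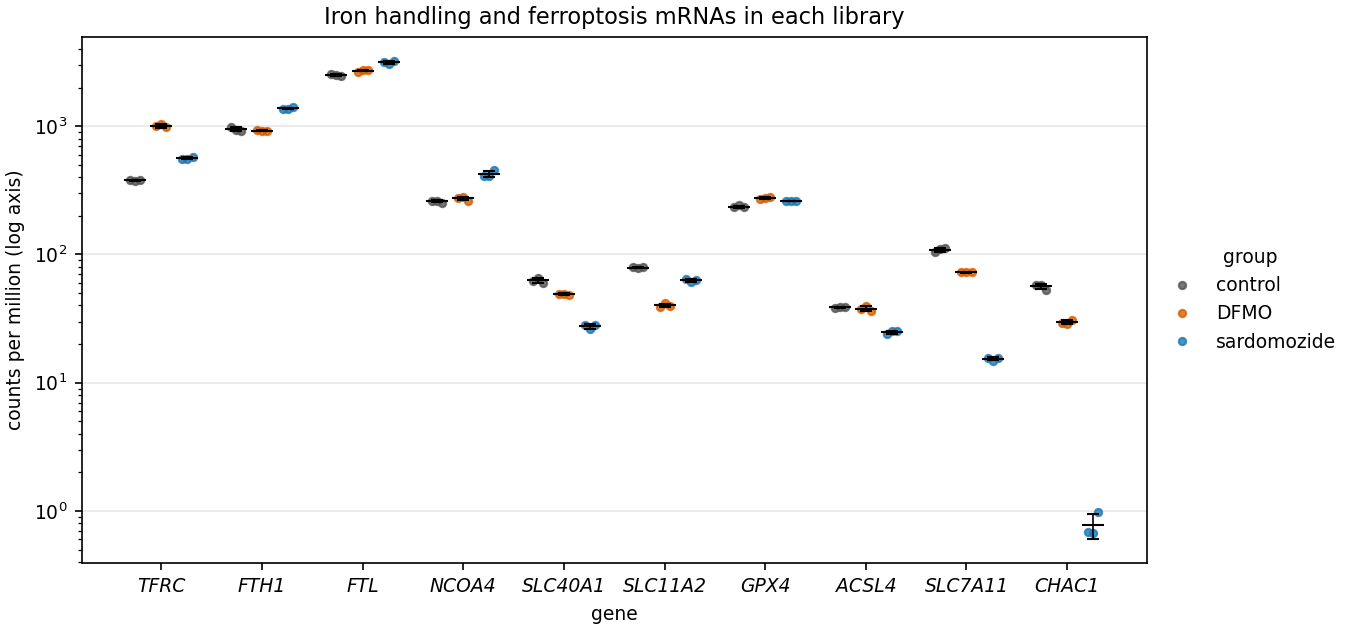
CPM of iron and ferroptosis genes, on a log axis, in each of the 9 libraries (points), with the mean and SD of the CPM of each group of 3. TFRC lies at 380, 1003 and 563 CPM in control, DFMO and sardomozide, and SLC7A11 at 109, 72.8 and 15.3 CPM.

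All 41 tested ATF4 and integrated stress response genes fell under sardomozide, with a median of -2.04 (camera adjusted p = 1.52e-18), and adjusted p = 0.09906 with an estimated correlation. DDIT4 was 51.8-fold lower, at 25.9 ± 0.61 CPM, the transcription factor ATF5 11.1-fold and the serine synthesis gene PSAT1 12.5-fold. Methionine and one-carbon genes fell in 16 of 28 cases and rose in 7 (median -0.28, adjusted p = 0.0218), with adjusted p = 0.3839 with an estimated correlation. The members with the smallest p-values, PHGDH, PSAT1, ALDH1L2 and MTHFD2, all stand in the ATF4 list as well, so this fall is not separate from that of the ATF4 list. Genes of the unfolded protein response fell in 15 of 25 cases and rose in 6 (median -0.29, adjusted p = 0.0222), with adjusted p = 0.5141 with an estimated correlation, and a median of -0.335 (-0.739 to 0.011) less genes matched on expression. HSPA5, the main chaperone of the endoplasmic reticulum, was 2.31-fold lower, and HERPUD1, a factor of protein degradation there, 5.85-fold lower. Of the cell cycle inhibitor and p53 target genes 14 of 24 fell and 6 rose (median -0.46, adjusted p = 0.0233), with adjusted p = 0.3194 with an estimated correlation, and a median of -0.732 (-1.046 to 0.028) less genes matched on expression. The cell cycle inhibitor CDKN1A changed by -3.33 and the apoptosis gene BBC3 was 6.80-fold lower.

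Erythroid, chaperone and ribosome biogenesis lists rose under sardomozide. In the globin and erythroid list 27 of 40 genes rose and 8 fell (median 0.48, camera adjusted p = 0.000704), with adjusted p = 0.2225 with an estimated correlation. Glycophorin B, GYPB, rose 4.95-fold, the blood group gene ERMAP 2.59-fold and delta globin, HBD, 9.38-fold, while related globin genes may share reads. The heme biosynthesis genes rose in 13 of 19 cases and fell in 5 (median 0.22, adjusted p = 0.0694, and 0.005959 with no low-count filter). MYC and ribosome biogenesis genes rose in 42 of 44 cases and fell in 2 (median 0.98, adjusted p = 3.228e-14), with adjusted p = 0.1493 with an estimated correlation. UTP20 and RRP9 rose 3.68-fold and 3.39-fold, whereas MYC itself was 1.85-fold lower (-0.89 ± 0.03). In the heat shock list 23 of 24 genes rose and 1 fell (median 0.84, adjusted p = 1.603e-08), with adjusted p = 0.3653 with an estimated correlation. HSPA8 rose 4.21-fold and DNAJA1 3.13-fold. Nuclear respiratory chain genes rose in 61 of 76 cases and fell in 7 (median 0.35, adjusted p = 4.431e-07), with adjusted p = 0.4569 with an estimated correlation, and ATP5MC1, a subunit of ATP synthase, rose 2.03-fold. Less genes matched on expression, the respiratory chain median was 0.19 (0.125 to 0.299). Iron-sulfur genes rose in 21 of 28 cases and fell in 5 (median 0.32, adjusted p = 0.00542), with adjusted p = 0.3839 with an estimated correlation, and a median of 0.094 (-0.097 to 0.376) less genes matched on length and expression. CIAO1, of the cytosolic assembly machinery, rose 1.73-fold. Lysosome and autophagy genes rose in 28 of 45 cases and fell in 12 (median 0.33, adjusted p = 0.0258), with adjusted p = 0.5097 with an estimated correlation and 0.153 with the strict filter. Less genes matched on expression their median was 0.221 (-0.095 to 0.348). The sialidase NEU1 rose 2.61-fold and the autophagy receptor SQSTM1 1.94-fold, while the autophagy kinase ULK1 changed by -1.43.

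Ribosomal protein, mitochondrial, cell cycle and histone transcripts fell under sardomozide. Of 76 cytosolic ribosomal protein genes 58 fell, 8 rose and 10 did not pass (59 and 8 adjusted over the list alone, median -0.28, camera adjusted p = 1.498e-05), with adjusted p = 0.6066 with an estimated correlation. RPL3 was 2.51-fold lower, at 879 ± 31.5 against 2207 ± 34.8 CPM, while RPS26 rose by 1.32 on the log2 scale. Of 13 genes of the mitochondrial genome 11 fell and 1 rose (median -0.68, adjusted p = 0.00256), with adjusted p = 0.5141 with an estimated correlation, and a median of -0.344 (-0.565 to 0.049) less genes matched on length and expression. MT-ND4 was 2.74-fold lower, whereas the share of counts from mitochondrial ribosomal RNA was 1.02 ± 0.03% against 0.73 ± 0.01% in control. Under DFMO that share was 0.37 ± 0.017%. In the S phase list 30 of 43 genes fell and 7 rose (median -0.20, adjusted p = 0.00316), with adjusted p = 0.6009 with an estimated correlation. In the G2 and M phase list 41 of 54 genes fell and 6 rose (42 and 6 adjusted over the list alone, median -0.41, adjusted p = 3.059e-06), with adjusted p = 0.3653 with an estimated correlation. The replication factor CDC45 changed by -0.87 ± 0.03, the topoisomerase TOP2A by -1.14 ± 0.03 and the mitotic kinase AURKB by -1.35 ± 0.04. Of 27 replication-dependent histone genes 24 fell and none rose, with a median of -2.004 (adjusted p = 8.453e-08, and adjusted p = 0.0215 with an estimated correlation). H1-2, on chromosome 6 from 26055787 to 26056428 (ENSG00000187837.4), stood at 50.7 ± 1.81 against 473 ± 6.52 CPM, and H2BC11 and H3C10 were 5.16-fold and 3.83-fold lower.

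By the naming rule, the largest rises under sardomozide were in PALM3, a paralemmin gene on chromosome 19 from 14053365 to 14059159 (ENSG00000187867.10), at 53.3 ± 0.71 against 3.08 ± 0.65 CPM (17.3-fold), and in the cell adhesion gene L1CAM (14.9-fold). PRDM11, CRYBG1, PHLDA1, the protein C receptor PROCR and the metalloprotease ADAM19 rose 8.01-fold to 11.4-fold. The largest falls were in INHBE, an inhibin subunit gene on chromosome 12 from 57452323 to 57459280 (ENSG00000139269.3), at 0.29 ± 0.10 against 48.4 ± 0.63 CPM (161-fold lower), and in ASS1, which makes argininosuccinate (102-fold lower). RGS3, AKNA, ALDH1L2, G0S2 and ADM2 were 29.9-fold to 45.5-fold lower. In all 12545 of 16947 genes passed, 6158 up and 6387 down. Among those that passed, the groups did not overlap in 12072. The 10% that chance gives for 3 against 3 does not apply to genes chosen by p-value. Of the changes of at least 2-fold, 1018 were rises and 2312 falls. The authors' deposited table gave 11365 genes at an adjusted p under 0.05, 5858 up and 5507 down, of which 10946 were called here with the same direction. Against a fold of 1.5, the count of calls was 4571. Lists named for sardomozide had the same counts adjusted over the list alone, apart from those stated.

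The direct comparison of sardomozide with DFMO asked where the drugs differ. AMD1, raised by both drugs, was 1.65-fold lower under sardomozide than under DFMO (log2 difference -0.72 ± 0.04, adjusted p = 1.851e-21). ODC1 was 1.84-fold lower and TFRC 1.78-fold lower under sardomozide, while FTH1 was 1.49-fold and OAZ2 3.53-fold higher. ALAS2 was 17.9-fold higher and HBZ 15.8-fold higher. CHAC1 was 37.8-fold lower and PHGDH 22.6-fold lower. OAZ1 and SRM were past the threshold in neither direction (-0.03 ± 0.03 and 0.05 ± 0.03, adjusted p = 0.383 and 0.218), SRM passing with no expression filter (0.09, adjusted p = 0.0155). Each of the drugs was tested at 1 dose and 1 time, so these differences hold for 1 mM DFMO and 5 uM sardomozide at 72 h.

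Lists that were lower under sardomozide than under DFMO included ribosomal proteins, with 72 of 76 genes lower and 1 higher (median -0.72, camera adjusted p = 3.555e-19, and adjusted p = 0.2861 with an estimated correlation). Less genes matched on length and expression, the ribosomal protein median was -0.299 (-0.379 to -0.212). RPL3 was 2.64-fold lower and RPL13A 2.36-fold lower. ATF4 targets were lower in 37 of 41 cases and higher in 2 (median -1.46, adjusted p = 9.336e-15), with adjusted p = 0.11 with an estimated correlation. G2 and M phase genes were lower in 46 of 54 cases and higher in 2 (median -0.56, adjusted p = 6.09e-12), with adjusted p = 0.1257 with an estimated correlation, and S phase genes in 40 of 43 with 1 higher (median -0.50, adjusted p = 9.21e-10), with adjusted p = 0.2861 with an estimated correlation. The ribonucleotide reductase subunit RRM2 was 2.85-fold lower, after a rise of 0.80 ± 0.04 under DFMO and a change of -0.71 ± 0.04 under sardomozide. Histone genes were lower in 26 of 27 cases and higher in 1 (median -1.39, adjusted p = 5.379e-07, and adjusted p = 0.03144 with an estimated correlation). Unfolded protein response genes were lower in 22 of 25 and higher in 2 (median -0.56, adjusted p = 1.206e-06), with adjusted p = 0.2011 with an estimated correlation. Methionine and one-carbon genes were lower in 22 of 28 and higher in 3 (median -0.39, adjusted p = 4.124e-05), with adjusted p = 0.1257 with an estimated correlation. Mitochondrial genome transcripts were lower in 11 of 13 and higher in 1 (median -0.71, adjusted p = 0.000249), with adjusted p = 0.4375 with an estimated correlation. Less genes matched on expression their median was -0.2 (-0.582 to 0.181), and less genes matched on length and expression 0.033 (-0.443 to 0.142). The respiratory chain list was lower in 47 of 76 genes and higher in 12 (47 and 13 adjusted over the list alone, median -0.18, adjusted p = 0.00452), with adjusted p = 0.6456 with an estimated correlation, and a median of -0.073 (-0.142 to 0.052) less genes matched on length and expression.

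Ferroptosis suppressors were lower under sardomozide than under DFMO in 22 of 34 cases and higher in 9 (23 and 9 adjusted over the list alone, median -0.32, camera adjusted p = 0.0121), with adjusted p = 0.4341 with an estimated correlation, and a median of -0.314 (-0.551 to 0.072) less genes matched on expression. SLC7A11 was 4.75-fold lower, CTH, which makes cysteine from cystathionine, changed by -1.9998, the desaturase SCD was 2.01-fold lower and thioredoxin reductase TXNRD1 1.85-fold lower. Higher under sardomozide were globin and erythroid genes in 32 of 40 cases with 4 lower (median 0.78, adjusted p = 4.418e-09), with adjusted p = 0.05063 with an estimated correlation. Heme biosynthesis genes were higher in 16 of 19 and lower in 2 (median 0.62, adjusted p = 8.675e-05), with adjusted p = 0.11 with an estimated correlation. The interferon-stimulated genes were higher in 12 of 19 and lower in none (11 adjusted over the list alone, median 0.48, adjusted p = 0.0149), with adjusted p = 0.1257 with an estimated correlation and 0.1275 with the strict filter. Polyamine genes were lower in 10 and higher in 4 of 23 cases (adjusted p = 0.192), and iron genes higher in 14 and lower in 10 of 27 (adjusted p = 0.462). In all 11434 genes passed, 5583 higher and 5851 lower under sardomozide. Among those that passed, the groups did not overlap in 10823. The 10% that chance gives for 3 against 3 does not apply to genes chosen by p-value. Against a fold of 1.5, the count was 3446. Counts adjusted over the list alone were otherwise those given.

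**Figure D3:**
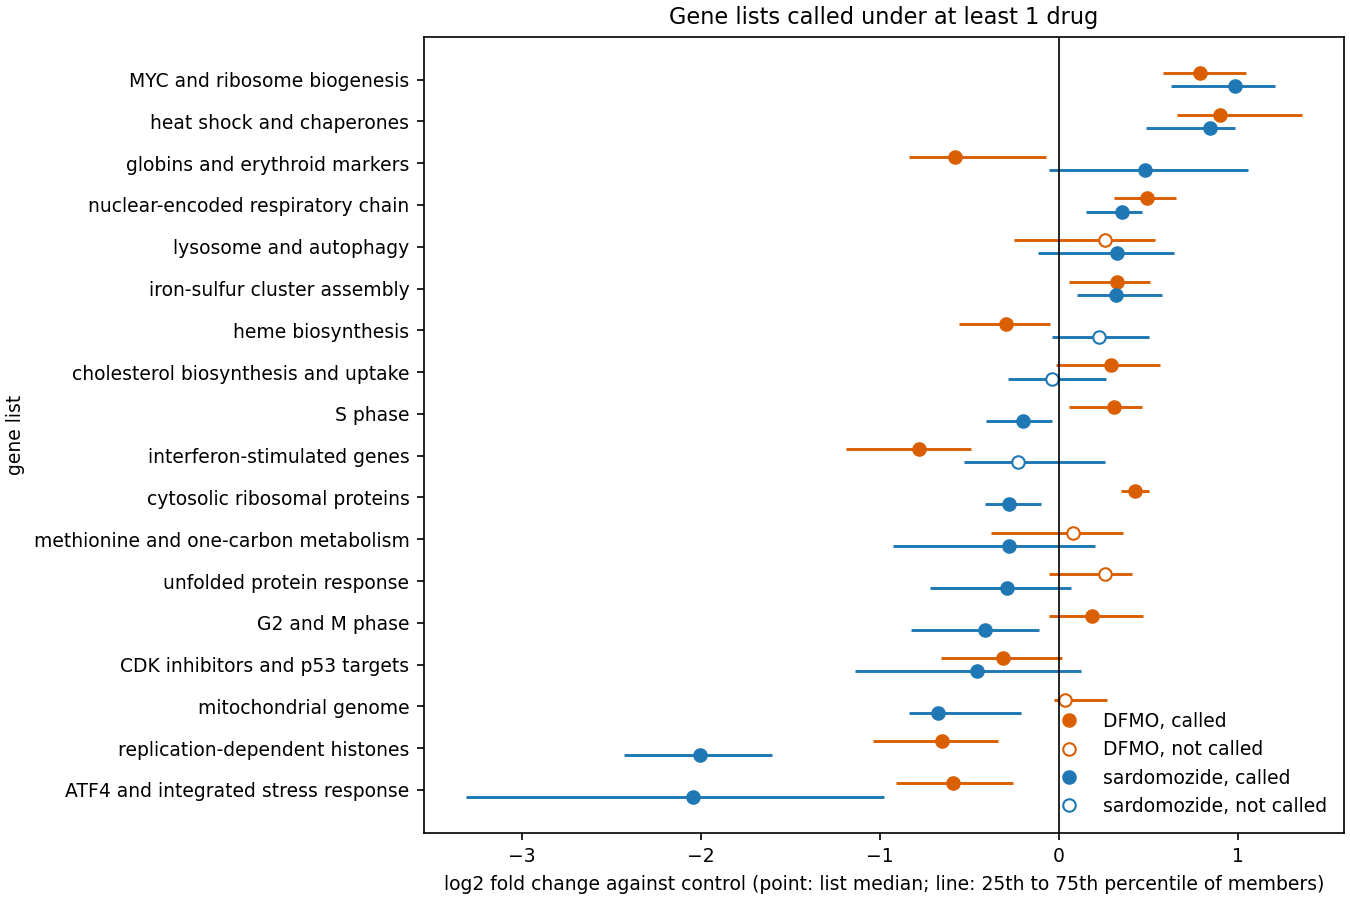
Median log2 change, for DFMO and for sardomozide against control, of the gene lists past the camera threshold under either drug or both. Filled points mark lists past the threshold under that drug, and lines span the quartiles of the members. Lists past the threshold under neither drug are not drawn. The ATF4 list lies at -0.59 and -2.04, ribosomal proteins at 0.42 and -0.28, and the globin and erythroid list at -0.58 and 0.48.

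Across the 16947 genes the changes under both drugs were related, with a Pearson r of 0.499 and a Spearman rho of 0.515. Both comparisons use the same controls, and 100 simulated sets of unchanged groups against those controls gave 0.469 ± 0.0145 and 0.424 ± 0.00757. The covariance of the changes was 0.363, against 0.0174 ± 0.000748 in the simulated sets, and 69.3% of genes had the same sign against 66.1 ± 0.364%. Both drugs raised 3634 genes and lowered 3713, where independent lists would share 2040 and 2200. Opposite calls were made for 995 genes up under DFMO and down under sardomozide and 985 the other way, where independent lists would give 2116 and 2121. In unchanged groups a shared control gives such correlations and shares of signs however small the noise, so these cannot show how far the drugs agree. The covariance keeps the size of the changes. Its 0.363 beside a simulated 0.0174 argues against the spread between the control libraries as its main source. The 3 controls could not be split with enough libraries on each side, so what the shared controls add to the excess of shared calls was not measured. Genes are not independent replicates.

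**Figure D4:**
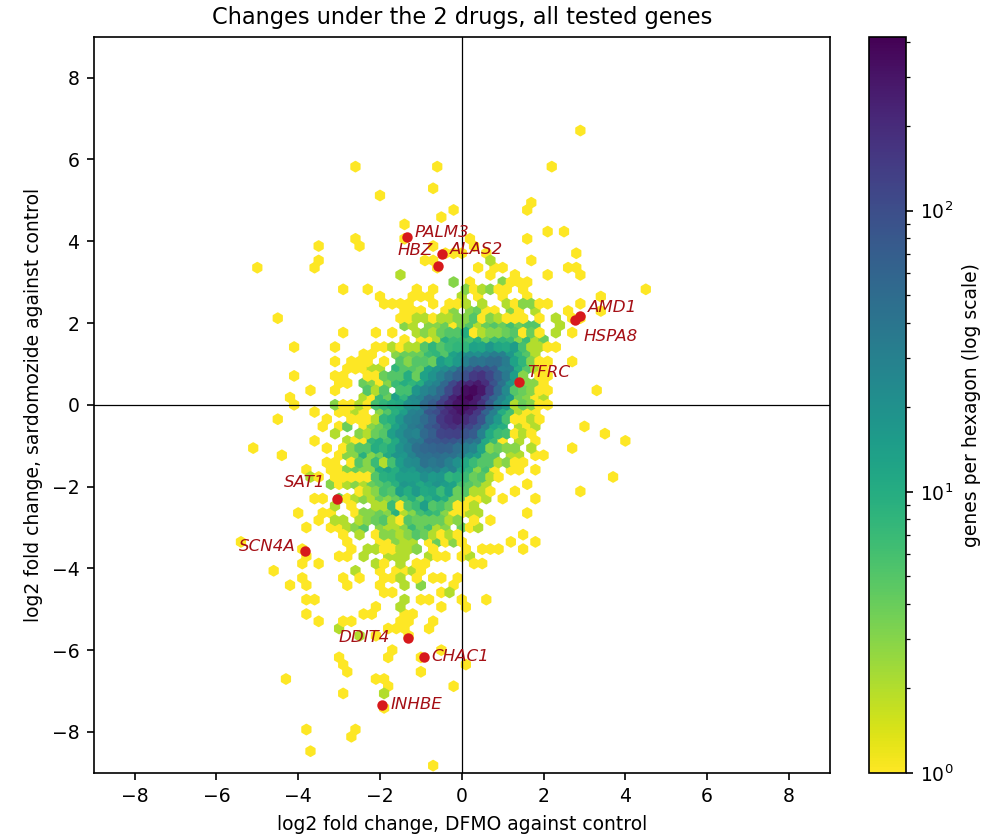
Log2 change under sardomozide (y axis) against log2 change under DFMO (x axis) for all 16947 tested genes, as hexagons coloured by the number of genes on a log scale, with named genes as red points. AMD1 and HSPA8 lie high on both axes, and CHAC1, DDIT4 and INHBE lie far lower on the sardomozide axis.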

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

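The length, GC content and poly(A) tests in this part were written before their results were seen, and the tests on expression level, S phase, iron-responsive elements and the splits of the libraries were chosen after.

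Ribosomal protein transcripts differed between the drugs (median log2 difference, sardomozide minus DFMO, -0.716, camera adjusted p = 3.555e-19, and adjusted p = 0.2861 with an estimated correlation), having risen under DFMO (0.425) and fallen under sardomozide (-0.278). For the fall, genes matched on expression, on length and expression or on GC content and expression did not move with them: the list lay -0.437 (95% interval -0.538 to -0.368), -0.335 (-0.402 to -0.268) and -0.444 (-0.531 to -0.378) below those genes, which argues against these properties as the cause. For the rise, the list lay 0.12 (0.045 to 0.183) above genes matched on expression, so those genes took up most of it. A relation of the change to expression level may account for this. However, only the list's own members were left out of the matched genes. These could include other genes that rose under DFMO, such as those of the respiratory chain. The match therefore cannot tell such a relation from a rise shared with those genes. Matching on length and expression left -0.007 (-0.048 to 0.066) and on GC content and expression 0.068 (0.02 to 0.107), which met what had been set beforehand for length and for GC content as the cause; the test on expression alone was added once these values were known, and since it also takes up most of the rise, length and GC content cannot be told apart from it. An effect of the drugs on these mRNAs stays open as a hypothesis, and the splits of the libraries do not bear on it.

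Replication-dependent histone transcripts fell under both drugs (medians -0.654 and -2.004), and their mRNAs lack poly(A) tails. Fewer cells in S phase could lower them. The S phase list had a median of 0.307 (0.14 to 0.382) under DFMO and -0.203 (-0.261 to -0.117) under sardomozide, each above the histone median. That meets what was set, after the data were seen, as counting against this account. Under DFMO the S phase genes moved the other way from the histones, with 29 of 43 up and 4 down. For the genes of this list, that argues against fewer cells in S phase as the account under DFMO. Under sardomozide both lists fell, and the criterion took them to fall by a like amount, which was not tested. It therefore cannot decide how far S phase contributes under sardomozide. Less carry-over of RNA without poly(A) tails could also lower the histone transcripts. Other such RNAs had medians of 1.297 under DFMO and 1.385 under sardomozide, which meets what had been set beforehand as counting against that account, but 3 of 30 were tested (RN7SL1, SNORA73B and SNORA53, at 0.154 to 9.21 CPM, of which the last pair are small nucleolar RNAs that lie in host genes), too few and too low to decide. Under sardomozide, carry-over, fewer cells in S phase and an effect of the drug on histone mRNA therefore cannot be told apart here. Under DFMO, carry-over and an effect of the drug cannot be told apart either.

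TFRC rose under both drugs (1.402 and 0.57). Its mRNA carries iron-responsive elements in the 3' untranslated region, through which low iron stabilises it, and such stabilisation might raise other mRNAs of this kind. Of the 4 tested, 2 rose under DFMO and 2 under sardomozide: TFRC and CDC14A (0.20 and 0.21) rose, while SLC11A2 (-0.98 and -0.33) and CDC42BPA (-0.48 and -0.26) fell. The criterion as first written took a fall of CDC42BPA, then held to carry the element in every isoform, as counting against the explanation, and its fall under both drugs met it. That criterion was replaced after the values were known by a bound of fewer than 2 rises, because counts per gene do not separate isoforms with and without the element, so the test decides nothing and the explanation cannot be told apart from others.

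Of the lists past the threshold in all 3 comparisons, 3 more had opposite directions under the drugs. Globin and erythroid genes differed by 0.776 (-0.58 under DFMO, 0.482 under sardomozide, adjusted p = 4.418e-09, and adjusted p = 0.05063 with an estimated correlation). S phase genes differed by -0.499 (0.307 and -0.203, adjusted p = 9.21e-10, and adjusted p = 0.2861 with an estimated correlation). G2 and M phase genes differed by -0.557 (0.186 and -0.412, adjusted p = 6.09e-12, and adjusted p = 0.1257 with an estimated correlation). Less genes matched on expression, the G2 and M phase median was -0.006 (-0.104 to 0.112) under DFMO and -0.565 (-0.827 to -0.376) under sardomozide. The rise under DFMO was thus no larger than in matched genes, and the strict filter ended that call.

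Each comparison has 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes: 11450 for DFMO, 12545 for sardomozide and 11434 for the direct comparison, where the highest other split gave 0. Every other split puts libraries of both groups on each side, so the difference between groups becomes spread within a side. With this many genes changed, few or no calls were bound to follow, so the 0 does not bear on false calls.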

How the results depend on the processing

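The comparisons with matched genes were chosen after the data were seen, and all other tests here before. Over the named genes, 4676 of the values under other settings kept direction and side of the threshold, 22 passed newly, 116 no longer passed (85 of them in the test against a fold of 1.5) and 0 reversed. Counts of genes past the threshold stayed within 1.5 times of the main count with every alternative but the test against a fold of 1.5, which gave 3182 (DFMO), 4571 (sardomozide) and 3446 (direct) because it asks for more. Leaving out 1 library gave 10716 to 11194, 12064 to 12402 and 10625 to 11322. DESeq2 gave 10650, 11763 and 10609, and RLE moved the median of all genes by at most 0.0166. Lists past the threshold numbered 14, 15 and 16 with camera. With an estimated correlation they were 0, 1 and 1, for which the cause was not tested, and with fry 26, 28 and 29, since fry does not compare a list with other genes. Lists not past the threshold in camera turned direction and passed in fry in 5 cases: iron (adjusted p = 0.006397) and ferroptosis promoters (0.04831) under DFMO and hypoxia under sardomozide (0.0001286) from up to down, and in the direct comparison selenoproteins from up to down (0.04748) and metallothioneins from down to up (0.0002594). The cause was not tested. Of 61 list tests that passed newly, 33 were with fry and 11 with no low-count filter, and the rest included the unfolded protein response and NF-kB lists under DFMO and the megakaryocyte, myeloid and lymphoid lists under sardomozide when 1 library was left out. Of 45 list calls, 9 had an interval across 0 beside genes matched on expression and 13 beside genes matched on length and expression, among them mitochondrial genome transcripts (-0.34 under sardomozide and 0.033 in the direct comparison, against -0.675 and -0.714 unmatched) and ferroptosis suppressors (-0.334, direct). No shared effect of the replicate number was seen: deviations of same-numbered libraries correlated at -0.061 to 0.016, and of differently numbered ones at -0.041 to 0.069. These values cannot show whether same-numbered cultures or preparations were handled together. A fit with the replicate block gave 11195, 12311 and 11155 genes, ended no list call, brought the lymphoid markers under sardomozide past the threshold (adjusted p = 0.04663) and ended the calls of SLC7A1 under DFMO and GPX4 in the direct comparison. Both of these gene calls lay near the threshold. They also ended with no low-count filter (adjusted p = 0.157 and 0.516), with DESeq2 (0.0591 and 0.0707) and when some single libraries were left out. Alternatives with pseudocounts were not run, as the tables hold counts. The smallest simulated changes were recovered in 60% to 70% of cases.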

Other observations

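The values in this part come from lists and comparisons fixed before the data were examined, and the tests of change by expression and of matched genes were chosen after the values were seen.

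In the list of NF-kB and early response genes, 18 of 29 rose and 8 fell under DFMO (median 0.39, camera adjusted p = 0.0594), 10 rose and 16 fell under sardomozide (median -0.39, adjusted p = 0.308), and 16 were lower and 5 higher under sardomozide than under DFMO (17 and 5 adjusted over the list alone, median -0.53, adjusted p = 0.0105), with adjusted p = 0.1257 with an estimated correlation. Less genes matched on length and expression the last median was -0.684 (-0.942 to 0.029). EGR1, an immediate early transcription factor, changed by -3.59 from DFMO to sardomozide, at 15.6 ± 0.19 against 188 ± 7.12 CPM, and SPRY4, an inhibitor of receptor kinase signalling, 6.13-fold lower. Fatty acid synthesis and desaturation genes were lower in 16 of 23 cases and higher in 6 (median -0.31, adjusted p = 0.0191), with adjusted p = 0.1257 with an estimated correlation, after 10 rises and 7 falls under DFMO (adjusted p = 0.749, median 0.02, mean -0.07, test up) and 9 rises and 13 falls under sardomozide (adjusted p = 0.137). Less genes matched on expression the difference between the drugs was -0.221 (-0.49 to 0.035). FADS2, a desaturase, was 2.34-fold lower and the lipid regulator SREBF1 1.63-fold lower. Of 5 lymphoid markers 3 were lower and 1 higher under sardomozide than under DFMO (camera adjusted p = 0.264). In the direct comparison CD3D, which is one of them, and CD69 were 36.4-fold and 23.1-fold lower under sardomozide, and CD69 stood at 43.8 ± 1.64 CPM under DFMO.

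Of 14 tested megakaryocyte genes 5 rose and 8 fell under DFMO (camera adjusted p = 0.696) and 3 rose and 10 fell under sardomozide (0.0554). Of 12 myeloid genes 1 rose and 7 fell under each drug (adjusted p = 0.0735 and 0.0594). Of 5 lymphoid genes 1 rose and 2 fell under DFMO (1 and 3 adjusted over the list alone, adjusted p = 0.724) and 4 fell under sardomozide (0.0548). The stromal and epithelial markers were lower in 8 of 10 cases and higher in 2 under sardomozide against DFMO (median -0.66, adjusted p = 0.0311), with adjusted p = 0.1437 with an estimated correlation, 0.05683 with no low-count filter and 0.11 with the strict filter, and a median of -1.166 (-1.996 to 0.212) less genes matched on expression. Fibronectin (FN1) was 7.36-fold and vimentin (VIM) 3.46-fold lower, while KRT19 was 2.44-fold higher and COL1A1 stood at 8.17 ± 1.34 against 0.31 ± 0.07 CPM.

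The remaining lists did not pass. Hypoxia genes rose in 15 and fell in 14 of 35 cases under DFMO (camera adjusted p = 0.724, median 0.02, mean -0.06, test up) and rose in 17 and fell in 12 under sardomozide (0.526, median 0.07, mean -0.15, test up). Selenoprotein genes rose in 7 and fell in 7 of 18 under DFMO (0.978, median 0.02, mean -0.20, test down) and rose in 6 and fell in 8 under sardomozide (0.85, median 0.003, mean -0.10, test down). Metallothionein and zinc genes rose in 4 and fell in 1 of 6 under DFMO (5 and 1 adjusted over the list alone, adjusted p = 0.212). Under sardomozide they rose in 3 and fell in 2 (0.708, median 0.055, mean -0.02, test up). Under DFMO, lysosome genes rose in 24 and fell in 15 of 45 (0.152), unfolded protein response genes rose in 16 and fell in 6 of 25 (0.0553), one-carbon genes rose in 14 and fell in 10 of 28 (0.696), and mitochondrial genome genes rose in 5 and fell in 2 of 13 (5 and 1 adjusted over the list alone, 0.366). Under sardomozide, cholesterol genes rose in 11 and fell in 11 of 25 (0.918, median -0.04, mean 0.02, test up) and interferon-stimulated genes rose in 6 and fell in 6 of 19 (0.904).

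The median change was tied to expression. Among the 677 genes above 8 on the log2 CPM scale it was 0.34 under DFMO and 0.04 under sardomozide, and among the 3171 genes from 6 to 8 it was 0.19 under each. Among the 2735 genes from 0 to 2 it was -0.27 and -0.31. Groups of 3 libraries are too small for the test of a library far from the others.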
